A study of Homo sapiens with 29 samples.

How the data were processed

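Gene-level counts were analysed from 29 libraries of orthotopic xenograft tumours. The tumours were grown in SCID-beige mice, which lack mature T and B cells, from MDA-MB-231, a human triple-negative breast cancer cell line, or from a paclitaxel-resistant derivative of it. Per the labels, libraries were made with the Lexogen QuantSeq forward kit after poly(A) selection. This method primes on the poly(A) tail and reads tags near the 3′ end, so that counts do not scale with transcript length, and RNA without such a tail is counted only as carry-over. The values deposited by the authors were raw counts per gene, as whole numbers that had not been normalised. Per the submitters' processing notes, cutadapt, STAR 2.7.3a and featureCounts were used with the genome build GRCh38.p10, and DESeq2 was also named. The annotation release, the strand setting of the counting and the handling of mouse reads were not given in the sources used here. Reads of near-identical copies (HLA class II, MAGE, SSX and U4 or U1 small nuclear RNA genes) and of overlapping or antisense genes could therefore have been split or joined, and values of such genes are uncertain. Reads of mouse stroma that aligned to human sequence would also have been counted.

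Groups were taken from the sample titles, and the numbers of libraries were 4 each in the parental vehicle, decitabine and combination groups, 3 in the parental doxorubicin group, 4 each in the resistant vehicle and doxorubicin groups, and 3 each in the resistant decitabine and combination groups. Replicates were separate samples as far as the labels say. Cells were injected on both sides of a mouse and the labels do not tie libraries to mice, so p-values measure the spread between these samples, some of which could share a mouse. Replicate numbers did not pair the libraries across groups, and no block was used. No pair of libraries of a group agreed within sampling noise (lowest chi-square per degree of freedom 3.65, genes with at least 10 counts). The experiment confounded the line with the number of cells injected and the day on which treatment started.

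Genes were filtered with filterByExpr (minimum count 10, minimum total 15), which left 13495 of 58302 genes. Counts were scaled by the trimmed mean of M-values, with factors from 0.896 to 1.07. All 29 libraries entered 1 quasi-likelihood fit with robust dispersion estimation in edgeR 4.0.16 under R 4.3.3, with 8 group means and contrasts between them. The common dispersion was 0.0304. P-values were adjusted by the Benjamini-Hochberg method within each contrast, and a gene was called at an adjusted p under 0.05. All adjusted p-values of genes are from this edgeR test unless another tool is named. Levels are CPM (counts relative to the scaled library size), as means ± SD. Fold changes are fitted log2 values with standard errors (SE). Against a group with no count, the fold was bounded with a floor of 3 counts over the group. With 1 to 3 counts, the ratio of counts was given with an exact 95% interval. Intervals and floors cover counting error only, since no molecular identifiers were used here.

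Gene lists were fixed before the data were examined: 32 lists with 809 entries. They covered cancer-testis genes, germline and meiosis genes, interferon-stimulated genes, antigen presentation, imprinted genes, p53 targets, DNA damage repair, ABC transporters, the neighbours of ABCB1 on chromosome 7, tubulins and microtubule proteins, epithelial, mesenchymal and luminal or basal breast genes, mitosis, DNA replication, the methylation machinery, nucleoside metabolism, inflammatory NF-kB targets, hypoxia and glycolysis, cholesterol synthesis, the unfolded protein response, NRF2 targets, apoptosis, nuclear oxidative phosphorylation genes, mitochondrially encoded genes, ribosomal proteins, and markers of fibroblasts, endothelium, myeloid cells, adipocytes, muscle and lymphocytes. Lists were tested with camera in limma 3.58.1 on voom values with a preset correlation of 0.01, adjusted over the lists of a contrast. Camera was repeated with an estimated correlation, and fry was also run. No list passed with an estimated correlation in any comparison. Beside the number of members called among all genes tested, the number called when p-values were adjusted over the list alone is given.

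The genes named were set by a rule written before the data were examined. It took the 10 largest changes per direction (5 for contrasts between treated groups and between the lines' responses) among called genes with at least 5 CPM in the higher group, no overlap between the groups and an official symbol. To these it added up to 4 called members of each list (or 2 members with their values where none was called), and ABCB1, ABCB4 and TUBB3 for resistance, DNMT1, DNMT3A and DNMT3B for decitabine, and TOP2A and CDKN1A for doxorubicin. Of the genes it selected, a part is printed. Whether calls held with 1 library left out was checked for a part of the selected genes, referred to below as those checked. The result of 1 selected gene is withheld and not reported here. Symbols came from a table of gene names, which matched 57532 identifiers. Positions came from GENCODE release 29 on GRCh38, which matched 58039.

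The steps were tested on simulated counts with the real means and library sizes. For decitabine in parental tumours, 66% of genes changed 2-fold and 92.9% of those changed 4-fold were recovered among 13394 genes. For doxorubicin in resistant tumours, the shares were 70% and 93.9% among 13428 genes. Preset alternatives were 2 other scalings, no filter and a laxer CPM filter (at least 1 CPM in 3 libraries of a group, 14466 genes). Others were DESeq2 1.42.0, voom with sample weights, a fit of the contrast's groups alone, a replicate block, and leaving out each library. An alternative without 2 libraries that stood apart was chosen after the data were seen.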

Results

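Transcript levels were measured in 29 libraries of xenograft tumours of MDA-MB-231 cells, a triple-negative breast cancer line with mesenchymal traits, and of a line derived from it that resists paclitaxel, a microtubule-stabilising drug. Mice received vehicle, decitabine (a cytidine analogue that traps DNA methyltransferases) at 0.4 mg/kg, doxorubicin (an anthracycline that poisons topoisomerase II) at 1 mg/kg, or both, over 26 days in 2 cycles of 12 days with 2 days of rest. The stated purpose was to ask whether resistance is tied to expression changes driven by DNA methylation and whether decitabine reverses them. Parental tumours arose from 250000 injected cells and were treated from day 6, and resistant tumours from 1500000 cells and from day 16, so the line could not be told apart from these settings. The libraries held between 3398261 and 5382295 counts, with a median of 4600007. Of 58302 genes in the table, 27963 had no count in any library, and the 13495 genes tested held 99.72% of the counts. In a principal component analysis of 2000 genes, PC1 (40.6% of the variance) placed the 15 parental libraries below 0 and the 14 resistant libraries above 0. On PC2 (13.2%), parental vehicle 3 at 34.6 and resistant decitabine 2 at 43.1 stood apart from the other libraries, which reached at most 20.6.

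Under vehicle, the question was how the resistant tumours differed from the parental tumours. LCP1, MAPT, several MAGE and HLA class II genes and inflammatory genes were higher in resistant tumours, and COL6A2, EPCAM, CDA and GSTP1 were lower. LCP1 (ENSG00000136167, chromosome 13, 46125920 to 46211871), an actin-bundling protein of blood cells that many carcinomas also express, rose from 2.68 ± 1.78 to 110.3 ± 10.8 CPM (SD, n = 4 each; log2 5.35, SE 0.33, adjusted p = 2.04e-11). The non-coding RNA LINC00470 had no count in the parental group and 241 in the resistant group, at least 81.6-fold higher. Levels of PTPRN2, a protein of secretory granules, were 17.35 ± 10.3 CPM against 1 count in the parental group, a ratio of 297 (95% interval 52.8 to 11800). The transcripts of ZNF354C, GABRE, KRBOX1 and TENM1 were at least 45.9-, 37.7-, 31.2- and 29.5-fold lower in the resistant group, which had no count of them. COL6A2, a collagen VI chain, was at 3 counts in the resistant group against 226 in the parental group, a ratio of 74.1 (95% interval 25.0 to 362).

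Of the 10 cancer-testis genes tested, which are normally restricted to germ cells and often silenced by DNA methylation elsewhere, 4 rose and 3 fell in the resistant line, with the same numbers adjusted over the list alone. The list as a whole did not pass (adjusted p = 0.372), and its median log2 was 0.70, or 0.48 with genes lacking counts in a group at their bound. MAGEC2 (ENSG00000046774, chromosome X, 142202345 to 142205290) rose from 12.06 ± 6.05 to 77.67 ± 9.87 CPM (log2 2.69, SE 0.32, adjusted p = 8.02e-07). SSX1 rose by 2.50 on the log2 scale (SE 0.54), and CTAG2, with 48 counts in the parental group and 0 in the resistant group, was at least 15.7-fold lower. Of 19 antigen presentation genes 6 rose and 1 fell (7 and 1 adjusted over the list alone; list adjusted p = 0.012, or adjusted p = 0.826 with an estimated correlation). HLA-DRA (ENSG00000204287, chromosome 6, 32439842 to 32445046), the α chain of the MHC class II molecule HLA-DR, rose from 1.57 ± 1.41 to 14.98 ± 3.14 CPM (log2 3.23, SE 0.50). Of 22 inflammatory NF-kB targets 9 rose and 1 fell, both over all genes and adjusted over the list alone (list adjusted p = 0.012, or adjusted p = 0.826 with an estimated correlation). SOD2, a mitochondrial superoxide dismutase, rose by 1.10 (SE 0.27), and ICAM1, an adhesion molecule, fell by 1.53 (SE 0.32). The antigen presentation list no longer passed without resistant vehicle 3 (adjusted p = 0.0537), nor the NF-kB list without resistant vehicle 1 (adjusted p = 0.0577). Both lymphocyte markers tested, IL7R and CD8A, rose, by 2.09 (SE 0.29) and 1.82 (SE 0.40). That list had an adjusted p = 0.0334, or adjusted p = 0.283 with an estimated correlation, and did not pass without parental vehicle 2 (0.0765) or resistant vehicle 1 (0.0577).

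ABCB1 (ENSG00000085563, chromosome 7, 87503633 to 87713323), the efflux pump for paclitaxel and doxorubicin, was barely counted, with 2 counts over the resistant group and 6 over the parental group, a ratio of 2.95 (95% interval 0.528 to 29.9). A difference was not detectable at this depth. ABCB4 had 2 and 4 counts, and TUBB3, a neuronal β-tubulin, had 1 and 2. Of 24 genes near ABCB1, 4 fell and 0 rose in the edgeR test (3 and 0 adjusted over the list alone), with a list adjusted p = 0.178. Of 11 ABC transporters, 2 rose (2 adjusted over the list alone), ABCC3 by 0.84 (SE 0.27) and ABCB9 by 0.55 (SE 0.18), and the list had an adjusted p = 0.467. Of 28 tubulin and microtubule genes, 2 rose and 4 fell (the same adjusted over the list alone; list adjusted p = 0.981, with a test below 0 and a median and mean above 0). MAPT (chromosome 17, 45894382 to 46028334), which encodes the microtubule-binding protein tau, rose from 15.64 ± 3.09 to 65.65 ± 13.1 CPM (log2 2.07, SE 0.19, adjusted p = 8.33e-09), and TUBB, the main β-tubulin, fell by 0.76 (SE 0.15). CDA, the deaminase that inactivates cytidine analogues, fell from 34.53 ± 7.33 to 6.63 ± 2.14 CPM (log2 -2.38, SE 0.27). DNMT1, the maintenance DNA methyltransferase, fell by 0.53 (SE 0.15), as did 2 others of 19 genes of the methylation machinery (3 adjusted over the list alone; list adjusted p = 0.372). Of 13 epithelial genes 2 rose and 5 fell (3 and 5 adjusted over the list alone; list adjusted p = 0.372), with EPCAM at -1.69 (SE 0.18) and MUC1 at 2.86 (SE 0.37), and of 23 mesenchymal genes 4 rose and 4 fell, also adjusted over the list alone (adjusted p = 0.893). GSTP1, a glutathione transferase, fell by 1.28 (SE 0.14), among 1 higher and 4 lower of 23 NRF2 targets, the same adjusted over the list alone (adjusted p = 0.893). That list's test was below 0 and its median (0.15) and mean above 0.

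In all, 2718 genes passed between the lines, 1168 higher and 1550 lower in resistant tumours, of which 471 and 351 changed by at least 1 on the log2 scale. The groups did not overlap for 22.3% of the genes tested, against 2.86% by chance. With 1 library left out, 43 of the 46 called genes among those checked were called in each fit. ABCC3 lost its call without parental vehicle 1 (adjusted p = 0.063), 2 or 3 (0.0674 each) or resistant vehicle 1 (0.113) or 3 (0.0603), ABCB9 without parental vehicle 1 (0.0879) or 2 (0.0606) or resistant vehicle 3 (0.0921), and DNMT1 without parental vehicle 2 (0.052) or resistant vehicle 3 (0.0686).

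**Figure D1:**
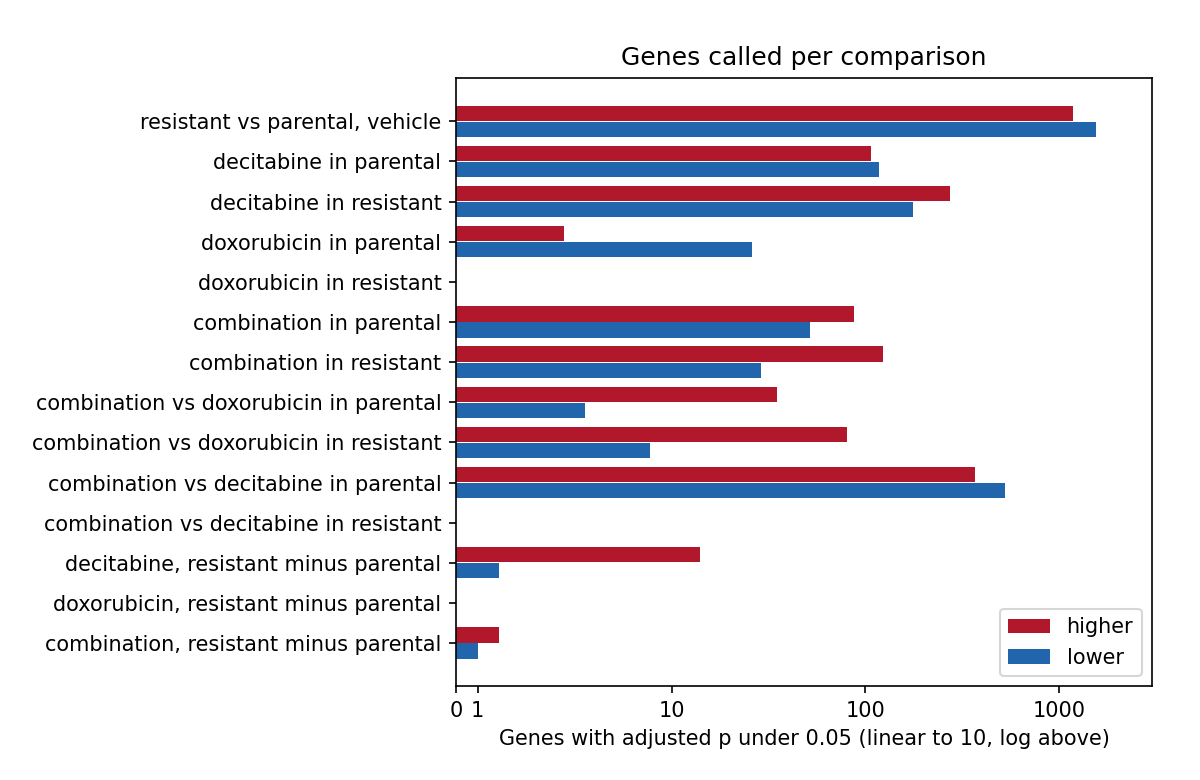
Genes called higher (red) and lower (blue) at an adjusted p under 0.05 in each comparison, as numbers of genes. The comparison of the lines has 1168 higher and 1550 lower genes, and 0 genes were called for doxorubicin in resistant tumours and for the combination against decitabine in resistant tumours.

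In parental tumours, genes raised by decitabine included FKBP10, CD70, OASL and BIRC5, and ITGA10 and FOS were among those lowered. FKBP10 (ENSG00000141756, chromosome 17, 41812680 to 41823217), a collagen-folding isomerase, rose from 0.73 ± 0.58 to 7.97 ± 2.96 CPM (n = 4 each; log2 3.46, SE 0.56, adjusted p = 0.00336). CD70, a ligand of the TNF family, rose by 3.19 (SE 0.59). ITGA10 (ENSG00000143127, chromosome 1, 145891208 to 145910189), an integrin subunit that binds collagen, fell from 56.58 ± 10.9 to 22.09 ± 7.32 CPM (log2 -1.36, SE 0.22, adjusted p = 0.00315). FOS, an immediate-early transcription factor, fell by 1.95 (SE 0.44), and RNU4-2 fell by 1.56 (SE 0.41). DNMT1, the target of the drug, was at 332.6 ± 29.6 CPM against 229.1 ± 38.9 and missed the threshold (log2 0.54, SE 0.15, adjusted p = 0.0516). DNMT3A and DNMT3B had log2 values of 0.08 (SE 0.18) and 0.49 (SE 0.35).

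Of 30 mitosis genes, 4 rose with decitabine in parental tumours over all genes and 26 adjusted over the list alone (median log2 0.61; list adjusted p = 6.97e-18, or adjusted p = 0.382 with an estimated correlation). BIRC5, an inhibitor of apoptosis that works at the centromere, rose by 0.80 (SE 0.17), and CDK1, the mitotic kinase, by 0.63 (SE 0.15). Of 30 replication genes 1 rose (7 adjusted over the list alone), and of 29 DNA repair genes 2 rose (7 adjusted over the list alone). Both lists had an adjusted p = 8.91e-09, or adjusted p = 0.382 with an estimated correlation. RRM2, a ribonucleotide reductase subunit, rose by 0.79 (SE 0.18), as 1 of 17 genes of nucleoside metabolism (4 adjusted over the list alone; list adjusted p = 0.198). Of 40 interferon-stimulated genes, 5 rose and 1 fell (9 and 3 adjusted over the list alone; list adjusted p = 0.00178, or adjusted p = 0.676 with an estimated correlation). OASL rose from 6.77 ± 2.15 to 22.12 ± 7.83 CPM and IFI44 from 23.86 ± 2.35 to 41.22 ± 8.95 CPM. That list did not pass without parental decitabine 2 (adjusted p = 0.299) or parental vehicle 1 (adjusted p = 0.189). No hypoxia or glycolysis gene of 29 was called by edgeR and 4 fell adjusted over the list alone (list adjusted p = 2.33e-08, or adjusted p = 0.539 with an estimated correlation; median log2 -0.52). Ribosomal protein genes were lower as a list (median log2 -0.168; adjusted p = 0.00762, or adjusted p = 0.676 with an estimated correlation), with 1 of 30 lower, also adjusted over the list alone, and the list did not pass without parental vehicle 4 (0.11). Of 28 p53 targets, FAS, a death receptor, rose by 1.67 (SE 0.44), and 2 rose adjusted over the list alone (list adjusted p = 0.245). Imprinted genes had 1 higher and 1 lower of 13 (1 and 3 adjusted over the list alone; list adjusted p = 0.736, with a test below 0 and a median and mean above 0), and the median of the 2 germline and meiosis genes tested was 0.96 (list adjusted p = 0.573). Of 8 myeloid markers, LAPTM5 and CTSS rose, by 0.85 (SE 0.19) and 1.20 (SE 0.27), and 4 rose adjusted over the list alone. The myeloid list had an adjusted p = 0.0482, or adjusted p = 0.382 with an estimated correlation, and did not pass without parental decitabine 2 (0.0509), 3 (0.193) or 4 (0.206) or parental vehicle 2 (0.178) or 4 (0.11), or with DESeq2's size factors (0.054).

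In all, 225 genes passed with decitabine in parental tumours, 107 higher and 118 lower, with 35 and 39 changed by at least 1 on the log2 scale. The share of higher genes, 47.6%, was 35.9% with upper quartile scaling. It turned to between 52.5% and 55.2% with DESeq2, its size factors, no filter or the CPM filter. Without parental decitabine 1, 2 or 3 or parental vehicle 1, 3 or 4 it was between 51.4% and 83.3%. Without the parental decitabine libraries the count became 99 (without 2), 6 (without 3) and 383 (without 4), and without the parental vehicle libraries 608 (without 1), 118 (without 2), 37 (without 3) and 12 (without 4). FKBP10 and ITGA10 stayed called in each such fit, and the 23 other called genes among those checked lost their call without parental decitabine 3. RNU4-2 lost its call in 8 of these 8 fits (adjusted p from 0.0566 to 0.237), FAS in 6 (up to 0.236), FOS, CTSS and CDK1 in 4 each (up to 0.175, 0.184 and 0.198), and BIRC5 and RRM2 in 3 each (up to 0.123 and 0.181). Without the 2 libraries that stood apart on PC2, 96 genes were called.

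In resistant tumours, decitabine raised genes that were almost uncounted under vehicle, among them NRIP3 and UCHL1. NRIP3 (ENSG00000175352, chromosome 11, 8980576 to 9004049), named for its interaction with nuclear receptors, was at 10.59 ± 1.9 CPM (n = 3) with decitabine and had no count in 4 vehicle libraries, at least 60.2-fold higher (adjusted p = 3.18e-07). UCHL1 (ENSG00000154277, chromosome 4, 41256413 to 41268455), a neuronal ubiquitin hydrolase, was at least 53.4-fold higher. ITGBL1, an integrin-like secreted protein, and TMEM204, a membrane protein of endothelium, had 75 and 101 counts with decitabine against 1 and 3 under vehicle, ratios of 96.8 (95% interval 16.9 to 3870) and 43.5 (14.5 to 214). FKBP10 rose by 3.29 (SE 0.42), the metalloprotease MMP9 by 3.27 (SE 0.55) and SPP1, osteopontin, by 3.26 (SE 0.47). SMOC1 and KCNU1, which were higher in resistant than in parental vehicle tumours, fell by 1.73 (SE 0.41) and 1.93 (SE 0.45). The small nuclear RNA genes RNVU1-27, RNU4-1 and RNU4-2 fell by 3.01, 2.16 and 1.63 (SE 0.65, 0.51 and 0.43). The log2 values of DNMT1, DNMT3A and DNMT3B were -0.22 (SE 0.16), 0.26 (SE 0.20) and 0.68 (SE 0.41), none of which passed.

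Of 40 interferon-stimulated genes, 11 rose with decitabine in resistant tumours and 29 adjusted over the list alone, with 0 lower (median log2 0.75; list adjusted p = 1.14e-18, or adjusted p = 0.196 with an estimated correlation). PARP14 (ENSG00000173193, chromosome 3, 122680618 to 122730840), an ADP-ribosyltransferase, rose from 46.48 ± 7.4 to 115.3 ± 9.52 CPM (log2 1.31, SE 0.18, adjusted p = 6.83e-05), and the RNA helicase DDX60 from 31.47 ± 5.38 to 76.29 ± 15.7 CPM. Of 10 cancer-testis genes, MAGEB2, CTAG2 and MAGEC1 rose, and 5 rose and 1 fell adjusted over the list alone (list adjusted p = 0.094). MAGEB2 had 66 counts against 2, a ratio of 42.6 (95% interval 11.3 to 359), and CTAG2 had 41 counts against 0, at least 17.6-fold higher. Of 30 ribosomal protein genes, 10 fell and 24 fell adjusted over the list alone (median log2 -0.54; list adjusted p = 5.1e-16, or adjusted p = 0.196 with an estimated correlation), among them RPLP2 by 0.59 (SE 0.12). Of 29 hypoxia and glycolysis genes, 5 fell and 20 fell adjusted over the list alone (median log2 -0.91; list adjusted p = 1.93e-14, or adjusted p = 0.278 with an estimated correlation). ENO1, LDHA and PGK1, enzymes of glycolysis, fell by 0.74 (SE 0.15), 0.90 (SE 0.19) and 0.92 (SE 0.26). Of 30 nuclear oxidative phosphorylation genes 2 fell (1 higher and 3 lower adjusted over the list alone), and of 24 genes of the unfolded protein response 0 were called by edgeR and 4 fell adjusted over the list alone. Both lists had an adjusted p = 0.00337, or adjusted p = 0.335 with an estimated correlation. The 13 mitochondrially encoded genes were higher as a list (median log2 0.23, adjusted p = 0.00298, or adjusted p = 0.278 with an estimated correlation), with 0 called and 2 higher adjusted over the list alone. They took 5.09% ± 0.329 of the counts with decitabine and 4.14% ± 0.229 under vehicle. CLDN4, a tight junction protein, rose by 1.41 (SE 0.18), and BIK, a pro-apoptotic protein, by 2.30 (SE 0.57), as 1 of 2 higher among 27 apoptosis genes (2 higher and 1 lower adjusted over the list alone; list adjusted p = 0.794). Among markers of other cell types, FCER1G and LAPTM5 of 8 myeloid genes rose, by 3.71 (SE 0.62) and 0.84 (SE 0.20), IL7R of 2 lymphoid genes rose by 0.94 (SE 0.26), and ENG of 8 endothelial genes rose by 1.26 (SE 0.25).

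In all, 450 genes passed with decitabine in resistant tumours, 274 higher and 176 lower, with 138 and 48 changed by at least 1 on the log2 scale. The count became 728, 146 and 282 without resistant decitabine 1, 2 and 3, and 287, 282 and 266 without resistant vehicle 1, 2 and 4. The share of higher genes, 60.9%, turned to 45.7% without a filter (498 higher and 591 lower) and was 80.1% without resistant decitabine 2 (117 and 29). Without resistant decitabine 2, 15 of the 41 called genes among those checked lost their call. Without both libraries that stood apart on PC2, 162 genes were called. In the 7 fits with 1 library left out, 23 of the 41 stayed called throughout, while PGK1 and MAGEC1 lost their call in 6 (adjusted p up to 0.269 and 0.105), RNU4-2 and IL7R in 5 (up to 0.209 and 0.108), and ENO1 and LDHA in 1, without resistant decitabine 2 (0.0572 and 0.0688). The lymphoid list, with an adjusted p = 0.0411, or adjusted p = 0.196 with an estimated correlation, did not pass without resistant decitabine 1 (0.124) or resistant vehicle 3 (0.0961).

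**Figure D2:**
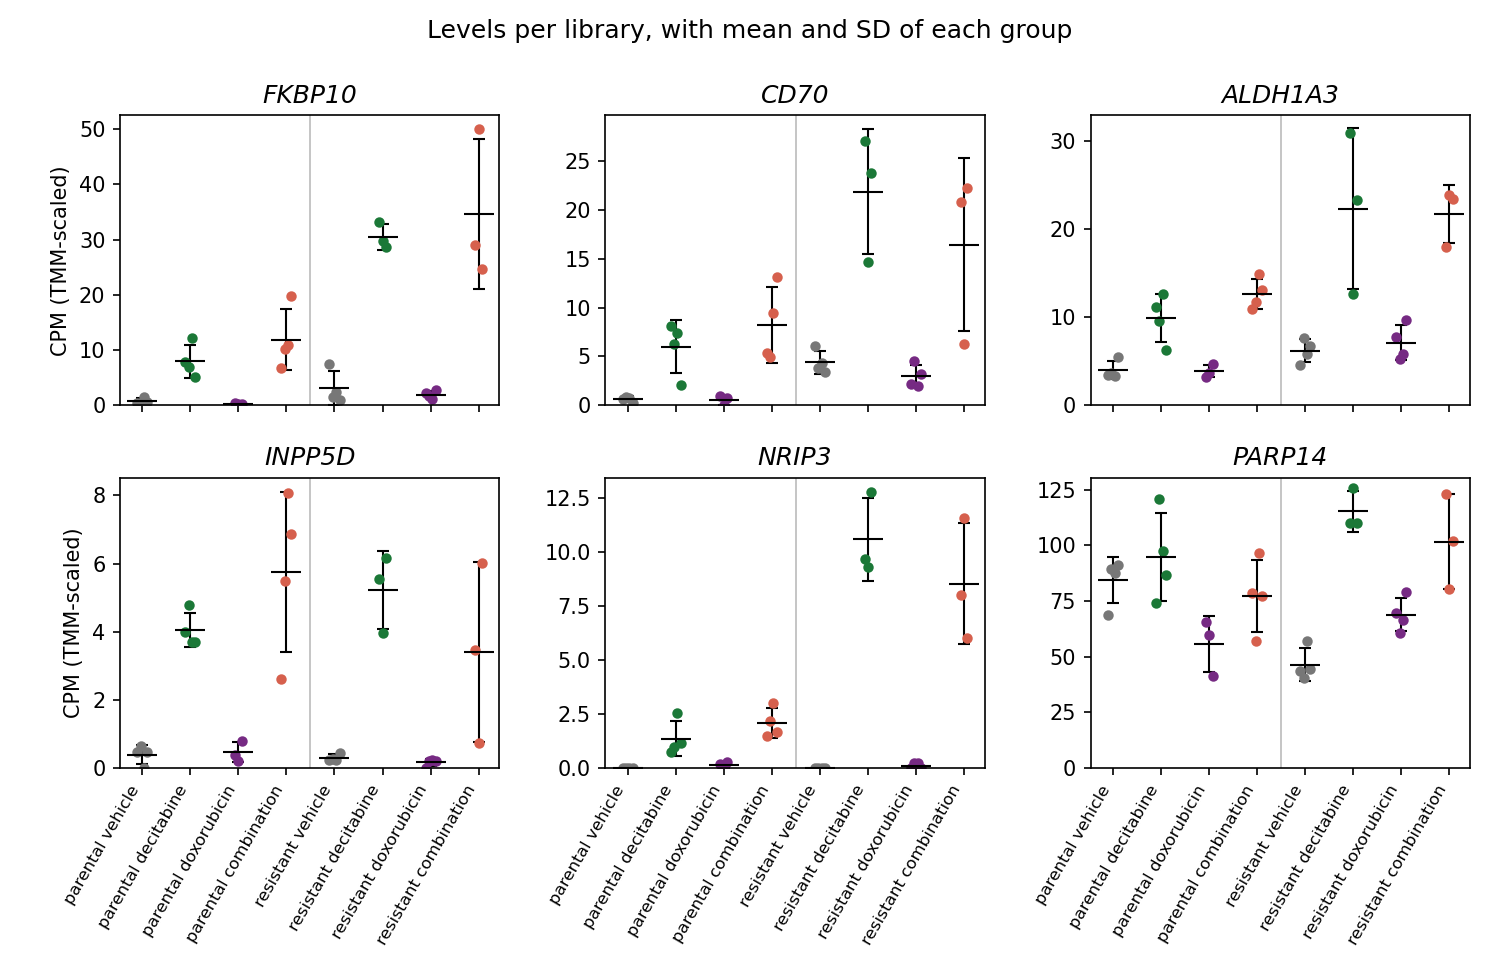
Levels of named genes in each library (points) and the group means with SD (bars), in CPM, for the 8 groups. NRIP3 had no count in resistant vehicle tumours and a mean of 10.59 CPM in resistant decitabine tumours.

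The 2 lines shared 20 genes raised and 8 lowered by decitabine, against 2.17 and 1.54 for independent lists of these sizes (Fisher's exact test, p = 3.49e-14 and 0.000154). Here and below, this test takes genes as independent. The lines have separate vehicle groups, and 2 genes lowered in parental tumours were raised in resistant tumours. Shared higher genes included NRIP3, CD93, INPP5D, FKBP10, CSF3, CDH13, CD70, ALDH1A3, IFI44 and LAPTM5, with FKBP10 at 3.46 and 3.29 and INPP5D, a lipid phosphatase of blood cells, at 3.24 and 4.04 on the log2 scale. The 28 shared genes became 14 without parental decitabine 2, 4 without parental decitabine 3, 17, 12 and 7 without parental vehicle 2, 3 and 4, 18 without resistant decitabine 2 or 3, and 15 without the 2 libraries that stood apart.

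Whether decitabine moved the differences between the lines back was examined with the resistant vehicle libraries divided between the contrasts. The 927 genes lower in the resistant line had a median decitabine log2 of 0.067 (0.042 to 0.091 over 6 divisions). Over 20 simulations without a decitabine effect it was 0.0030 (-0.0048 to 0.020). The 744 genes higher there had a median of -0.025 (-0.031 to 0.021), against 0.0058 in simulated counts. Without parental vehicle 3 the medians of lower and higher genes were 0.035 and 0.055, and 0.034 and 0.001 without resistant decitabine 2. The lower genes had 0.092 without resistant decitabine 1. Simulated counts may lack spread shared by genes, so no reversal was concluded. In the median division, 12.5 of the lower genes rose with decitabine and 3 fell, and 8 of the higher genes rose and 8 fell. With all vehicle libraries in both contrasts, 66 of the 1550 lower genes rose and 16 fell (median 0.13, simulated 0.054). Of the 1168 higher genes 32 rose and 39 fell there (median -0.108, simulated -0.0723). CTAG2 and CLDN4 were among the named genes lower in the resistant line and raised by decitabine.

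In parental tumours, doxorubicin changed few genes. TNNT1 (ENSG00000105048, chromosome 19, 55132794 to 55149354), a slow skeletal muscle troponin, rose from 68.53 ± 4.71 (n = 4) to 118.6 ± 19.4 CPM (n = 3; log2 0.79, SE 0.13, adjusted p = 0.00749). MMP16 (ENSG00000156103, chromosome 8, 88032009 to 88328025), a membrane metalloprotease, fell from 17.61 ± 1.09 to 6.95 ± 2.81 CPM (log2 -1.32, SE 0.22, adjusted p = 0.00749). PURPL, a non-coding RNA that restrains p53, fell by 1.88 (SE 0.37), and MIR100HG, the host transcript of microRNA genes, by 1.13 (SE 0.22). TOP2A, the target of the drug, was at 898.6 ± 127 CPM against 850.3 ± 128 (log2 0.08, SE 0.16), and CDKN1A, the p53-induced cell cycle inhibitor, at 92.39 ± 45.7 CPM against 55.48 ± 13.7 (log2 0.73, SE 0.21, adjusted p = 0.131). AKAP9, a centrosomal anchoring protein near ABCB1, fell by 0.65 (SE 0.13), as 1 of 24 neighbours of that gene (2 adjusted over the list alone; list adjusted p = 0.0104, or adjusted p = 0.649 with an estimated correlation). The 40 interferon-stimulated genes were lower as a list (median log2 -0.185; adjusted p = 0.0104, or adjusted p = 0.791 with an estimated correlation), which did not pass without parental doxorubicin 3 (0.746) or parental vehicle 2 (0.14) or 4 (0.164). Ribosomal protein (median 0.18), nuclear oxidative phosphorylation (0.189) and hypoxia genes (0.251) were higher as lists (adjusted p = 0.00288 each). So were cholesterol synthesis (0.205), tubulin (0.171) and mitochondrially encoded genes (0.177; adjusted p = 0.00624, 0.0177 and 0.0354). These 6 lists had an adjusted p = 0.649 to 0.791 with an estimated correlation. In these 7 lists 0 genes were called by edgeR or adjusted over the list alone. Mitochondrially encoded genes took 4.06% ± 0.273 of the counts with doxorubicin and 3.91% ± 0.167 under vehicle. Ribosomal proteins did not pass without parental doxorubicin 3 (0.0796) or parental vehicle 3 (0.0568), hypoxia without parental doxorubicin 3 (0.118), nor cholesterol synthesis without parental doxorubicin 1 (0.16) or parental vehicle 4 (0.164). Tubulin did not pass without parental doxorubicin 1 (0.0642) or 3 (0.095) or parental vehicle 4 (0.0701), nor mitochondrially encoded genes without parental doxorubicin 3 (0.395) or parental vehicle 2 (0.236) or 3 (0.0733). In all, 31 genes passed, 5 higher and 26 lower, with 6 higher and 4 lower without parental doxorubicin 1 and 4 each without 2. The count became 10, 8 and 1 without parental doxorubicin 1, 2 and 3, and 4, 124, 3 and 6 without parental vehicle 1, 2, 3 and 4. Of the 12 called genes among those checked, 0 stayed called throughout. Without the 2 libraries that stood apart, 3 genes were called.

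In resistant tumours, doxorubicin changed 0 genes in the edgeR test, with 591 genes at an unadjusted p under 0.05, 0 genes by DESeq2 and 1 by voom with sample weights. TOP2A was at 878.4 ± 158 CPM against 913.3 ± 109 (n = 4 each; log2 -0.06, SE 0.15) and CDKN1A at 74.36 ± 11.7 against 74.68 ± 6.49 (log2 -0.01, SE 0.19). The 40 interferon-stimulated genes were higher as a list (median log2 0.51; adjusted p = 1.56e-15, or adjusted p = 0.223 with an estimated correlation), with 0 called adjusted over the list alone. PARP14 was at 68.96 ± 7.6 CPM against 46.48 ± 7.4 (log2 0.57, SE 0.17). The difference from the response in parental tumours, where this list was lower, had a median of 0.732 (adjusted p = 3.9e-11, or adjusted p = 0.606 with an estimated correlation). The antigen presentation list was also higher (adjusted p = 0.000206, or adjusted p = 0.313 with an estimated correlation), with HLA-DRA at 41.44 ± 21.5 CPM against 14.98 ± 3.14 and 1 gene higher adjusted over the list alone. Markers of fibroblasts were lower (12 genes, median log2 -0.48; adjusted p = 0.000103, or adjusted p = 0.223 with an estimated correlation), as were 4 adipocyte markers (median log2 -0.89; adjusted p = 0.0105, or adjusted p = 0.176 with an estimated correlation). Neither list had a called gene by edgeR, and 0 and 2 genes were lower adjusted over the list alone. The 2 lymphoid markers, IL7R and CD8A, were higher as a list (median log2 0.449; adjusted p = 0.0459, or adjusted p = 0.223 with an estimated correlation; 1 higher adjusted over the list alone), which did not pass without resistant doxorubicin 1 (0.0955) or 3 (0.144) or resistant vehicle 3 (0.209) or 4 (0.0649). NF-kB targets (median 0.199) and mitochondrially encoded genes (0.176) were also higher as lists (adjusted p = 0.00117 and 0.000765, or adjusted p = 0.466 and 0.223 with an estimated correlation). The latter took 4.55% ± 0.188 of the counts against 4.14% ± 0.229. Replication (median -0.175), mesenchymal (-0.112) and hypoxia genes (-0.0908) were lower as lists (adjusted p = 0.00821, 0.0459 and 0.0459, or adjusted p = 0.642, 0.557 and 0.75 with an estimated correlation). In these 5 lists 0 genes were called by edgeR or adjusted over the list alone. NF-kB targets did not pass without resistant doxorubicin 1 (0.109) or resistant vehicle 4 (0.0581), nor replication without resistant doxorubicin 1 (0.094) or 2 (0.119) or resistant vehicle 4 (0.337). Mesenchymal genes did not pass without resistant doxorubicin 1 (0.0881), 3 (0.118) or 4 (0.144) or resistant vehicle 2 (0.104) or 3 (0.323), nor hypoxia without resistant doxorubicin 3 (0.831, with the direction turned) or resistant vehicle 3 (0.678).

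In parental tumours with the combination, INPP5D (ENSG00000168918, chromosome 2, 233059967 to 233207903) rose from 0.39 ± 0.28 to 5.76 ± 2.35 CPM (n = 4 each; log2 3.74, SE 0.53, adjusted p = 0.000278), FKBP10 by 4.03 (SE 0.54) and CD70 by 3.62 (SE 0.57). AQP1, a water channel, rose by 2.27 (SE 0.33), and TNFSF10, the death ligand TRAIL, by 1.85 (SE 0.33). HLA-B (ENSG00000234745, chromosome 6, 31269491 to 31357188) rose from 509.3 ± 150 to 1196 ± 89.7 CPM (log2 1.23, SE 0.20, adjusted p = 0.00173). PURPL and FANCB, a Fanconi anaemia protein, fell by 1.58 (SE 0.32) and 1.56 (SE 0.36). Of 22 NF-kB targets 3 rose and 12 rose adjusted over the list alone (list adjusted p = 2.92e-07, or adjusted p = 0.297 with an estimated correlation), with ICAM1 at 1.41 (SE 0.27) and SOD2 at 1.35 (SE 0.27). Of 19 antigen presentation genes 3 rose (9 adjusted over the list alone; list adjusted p = 2.04e-06, or adjusted p = 0.297 with an estimated correlation). Of 40 interferon-stimulated genes 6 rose (10 adjusted over the list alone; list adjusted p = 2.38e-06, or adjusted p = 0.53 with an estimated correlation), IFIT2 by 1.17 (SE 0.21). MAGEB2 had 30 counts against 0, at least 8.5-fold higher, as the 1 gene called of 10 cancer-testis genes (1 adjusted over the list alone; list adjusted p = 0.0112, or adjusted p = 0.397 with an estimated correlation), and that list did not pass without parental vehicle 2 (0.0522). Of 27 apoptosis genes 1 rose (4 adjusted over the list alone; list adjusted p = 0.0435, or adjusted p = 0.297 with an estimated correlation). Of 24 neighbours of ABCB1 1 fell (5 adjusted over the list alone; list adjusted p = 0.0239, or adjusted p = 0.397 with an estimated correlation). Mitosis (median -0.243) and replication genes (-0.184) were lower as lists (adjusted p = 0.0262 and 0.00908). Hypoxia (0.342), oxidative phosphorylation (0.175) and ribosomal protein genes (0.143) were higher (adjusted p = 0.0142, 0.041 and 0.0301). These 5 lists had an adjusted p = 0.611 to 0.658 with an estimated correlation, 0 genes called by edgeR and 1 hypoxia gene higher adjusted over the list alone. Apoptosis did not pass without parental combination 3 (0.0628) or 4 (0.0761) or parental vehicle 1 (0.0653), 3 (0.0738) or 4 (0.0592). Without parental combination 4, the neighbours of ABCB1 and replication (0.0592 each) and mitosis (0.1) did not pass, nor without parental vehicle 1 (0.0812, 0.153 and 0.622), and mitosis also not without parental vehicle 3 (0.0738). Hypoxia did not pass without parental combination 2 (0.161) or parental vehicle 1 (0.0708). Oxidative phosphorylation did not pass without parental combination 2 (0.109) or 4 (0.141) or parental vehicle 3 (0.128) or 4 (0.0568), nor ribosomal proteins without parental combination 2 (0.162) or 4 (0.17) or parental vehicle 1 (0.0653) or 3 (0.131). In all, 139 genes passed, 87 higher and 52 lower. The count became 65, 55 and 80 without parental combination 1, 2 and 4, 66 and 53 without parental vehicle 1 and 3, and 85 without the 2 libraries that stood apart. Of the 26 called genes among those checked, 12 stayed called throughout, and 10 lost their call without parental vehicle 3. FANCB lost its call in 5 of 8 fits with 1 library left out (adjusted p up to 0.124).

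In resistant tumours, the combination also raised genes that were uncounted under vehicle. NRIP3 and CD93 (ENSG00000125810, chromosome 20, 23079349 to 23086340), a receptor of endothelial and myeloid cells, were at 8.55 ± 2.82 and 5.73 ± 2.16 CPM (n = 3) and had no count in 4 vehicle libraries, at least 47.2- and 31.6-fold higher. FILIP1, a filamin-binding protein, rose by 4.30 (SE 0.48), FKBP10 by 3.47 (SE 0.42), CSF3, a granulocyte growth factor, by 2.77 (SE 0.48) and CDH13, a cadherin without a cytoplasmic domain, by 2.37 (SE 0.28). SMOC1 fell by 2.44 (SE 0.43), NEGR1 by 1.28 (SE 0.26) and DKK1, a Wnt antagonist, by 0.99 (SE 0.24). Of 40 interferon-stimulated genes 9 rose and 26 rose adjusted over the list alone (median log2 0.72; list adjusted p = 1.41e-20, or adjusted p = 0.312 with an estimated correlation), with OAS2 at 56.31 ± 20.9 CPM against 21.72 ± 9.9. Ribosomal protein genes were lower as a list (median log2 -0.31; adjusted p = 6.76e-09, or adjusted p = 0.368 with an estimated correlation), with 0 of 30 called by edgeR and 0 adjusted over the list alone. The 13 mitochondrially encoded genes were higher as a list (median log2 0.134; adjusted p = 0.0361, or adjusted p = 0.451 with an estimated correlation; 0 called and 1 higher adjusted over the list alone) and took 4.70% ± 0.532 of the counts against 4.14% ± 0.229. That list did not pass without resistant combination 2 (0.405) or resistant vehicle 1 (0.0551) or 2 (0.116). Antigen presentation genes were higher as a list (median log2 0.529; adjusted p = 0.000213, or adjusted p = 0.368 with an estimated correlation), with 0 of 19 called and 4 higher adjusted over the list alone. Of 22 NF-kB targets 3 rose (6 adjusted over the list alone; list adjusted p = 0.00111, or adjusted p = 0.451 with an estimated correlation), and the list did not pass without resistant combination 3 (0.0664). Hypoxia (median -0.311), methylation machinery (-0.145), mitosis (-0.18) and oxidative phosphorylation genes (-0.256) were lower as lists (adjusted p = 0.000259, 0.0134, 0.0199 and 0.0429, or adjusted p = 0.62, 0.312, 0.659 and 0.579 with an estimated correlation), with 0 genes called by edgeR or adjusted over the list alone. Methylation machinery did not pass without resistant combination 1 (0.0685), nor mitosis without resistant combination 1 (0.172) or 3 (0.27) or resistant vehicle 2 (0.14) or 4 (0.401). Oxidative phosphorylation did not pass without resistant combination 1 (0.101) or resistant vehicle 1 (0.0699), 3 (0.06) or 4 (0.172). Among markers of other cell types, PECAM1 of 8 endothelial genes rose by 1.47 (SE 0.26), and 4 rose adjusted over the list alone (list adjusted p = 0.00964, or adjusted p = 0.312 with an estimated correlation). FCER1G of 8 myeloid genes rose by 2.68 (SE 0.69), and 2 rose adjusted over the list alone (list adjusted p = 0.0199, or adjusted p = 0.312 with an estimated correlation). The endothelial list did not pass without resistant combination 2 (0.0595) or resistant vehicle 3 (0.0605), nor the myeloid list without resistant vehicle 1 (0.0551) or 3 (0.0624). In all, 152 genes passed, 123 higher and 29 lower, which turned to 351 higher and 432 lower without a filter. The count became 49 without resistant combination 1, and 88, 63 and 65 without resistant vehicle 1, 2 and 4. It was 363 without the 2 libraries that stood apart, which belong to neither group and act only through the shared fit. Of the 26 called genes among those checked, 15 stayed called throughout, and 10 lost their call without resistant combination 1. DKK1 and FCER1G lost their call in 6 of 7 fits with 1 library left out (adjusted p up to 0.177 and 0.164), and OAS2 in 4 (up to 0.258). The 2 lines shared 26 raised and 2 lowered genes, against 0.793 and 0.112 for independent lists (Fisher's exact test, p = 3.59e-33 and 0.00553). Of genes raised and lowered in parental tumours, 88.5% and 44.2% kept their sign in resistant tumours.

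**Figure D3:**
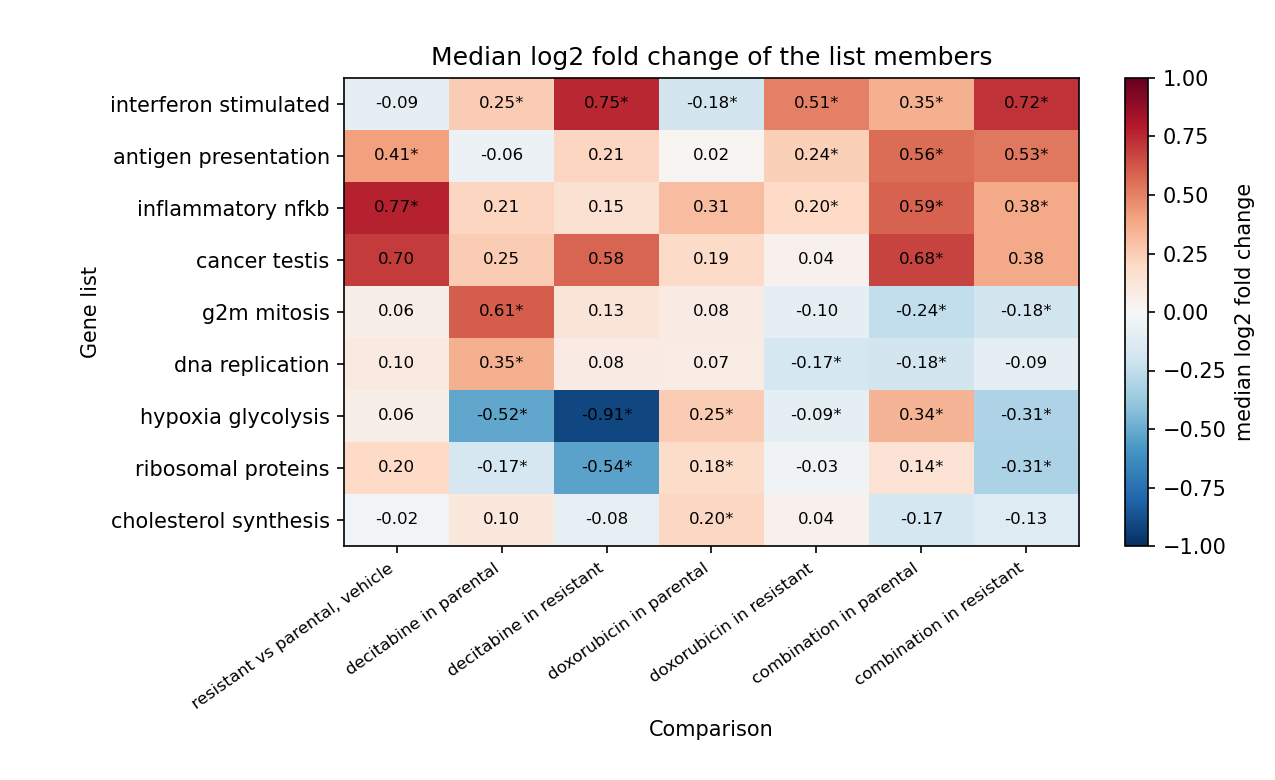
Median log2 change of each gene list (rows) in each comparison (columns), with an asterisk for lists that passed with the preset correlation. Interferon-stimulated genes have medians of 0.75 with decitabine and 0.72 with the combination in resistant tumours, and hypoxia and glycolysis genes a median of -0.91 with decitabine in resistant tumours.

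Adding decitabine to doxorubicin raised FKBP10 by 5.21 (SE 0.69), CD70 by 3.74 (SE 0.64) and INPP5D by 3.61 (SE 0.57) in parental tumours (n = 4 against 3), and TCN1, a vitamin B12 carrier, by 2.19 (SE 0.40). NFATC4, a transcription factor activated by calcineurin, fell by 1.04 (SE 0.23) and CCDC80, a matrix protein, by 0.76 (SE 0.16). Of 41 genes called there, 35 were higher, and the count became 15 and 18 without parental combination 2 and 4, and 15, 15 and 7 without parental doxorubicin 1, 2 and 3. NFATC4 lost its call in 7 of these 7 fits (adjusted p from 0.0644 to 0.226) and CCDC80 in 4 (up to 0.372). Among those checked, 2 of the 7 called genes stayed called throughout. Interferon-stimulated genes had 2 of 40 higher and 19 adjusted over the list alone (list adjusted p = 2.13e-16, or adjusted p = 0.16 with an estimated correlation). In resistant tumours (n = 3 against 4), CD93 had 77 counts against 0, at least 35.1-fold higher, NRIP3 had 115 counts against 2, a ratio of 78.7 (95% interval 21.3 to 658), and FKBP10 rose by 4.12 (SE 0.44). MT2A, a metallothionein, fell by 0.80 (SE 0.15). Of 89 genes called, 80 were higher (287 higher and 256 lower without a filter), and the count became 52 and 59 without resistant doxorubicin 1 and 2. Of the 10 called genes among those checked, 5 stayed called throughout. Endothelial and myeloid markers had 1 gene each higher (6 and 3 adjusted over the list alone; list adjusted p = 0.000386 and 0.000593, or adjusted p = 0.106 for both with an estimated correlation). Without the 2 libraries that stood apart, 65 genes were called in parental and 193 in resistant tumours.

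Mitosis and replication genes were lower with the combination than with decitabine alone in parental tumours. FAM111B (ENSG00000189057, chromosome 11, 59107185 to 59127410), a protease of replicating cells, fell from 68.6 ± 19.8 to 19.83 ± 4.56 CPM (n = 4 each; log2 -1.79, SE 0.27, adjusted p = 0.00161). ESCO2, the acetyltransferase of sister chromatid cohesion, fell by 1.65 (SE 0.28) and FANCB by 1.72 (SE 0.35). EGLN3, an oxygen-sensing hydroxylase, rose by 1.85 (SE 0.42), the creatine transporter SLC6A8 by 1.97 (SE 0.36), and RNU4-2 by 1.80 (SE 0.40). Of 30 mitosis genes 22 fell (27 adjusted over the list alone; list adjusted p = 3.03e-23), and of 30 replication genes 15 fell (23 adjusted over the list alone; list adjusted p = 7.81e-16), and both had an adjusted p = 0.129 with an estimated correlation. Of 29 hypoxia and glycolysis genes 8 rose (21 adjusted over the list alone; list adjusted p = 6.6e-14, or adjusted p = 0.243 with an estimated correlation). In all, 895 genes passed, 369 higher and 526 lower, and the count became 525 and 364 without parental combination 1 and 2, and 210 and 579 without parental decitabine 3 and 4. Of the 9 called genes among those checked, 4 stayed called throughout. RNU4-2 lost its call in 2 of 8 fits (adjusted p up to 0.062) and EGLN3 in 1 (0.0551). In resistant tumours (n = 3 each), 0 genes passed in the edgeR test, with 504 at an unadjusted p under 0.05 and 0 by DESeq2. The mitosis list was lower there as well (median log2 -0.30; adjusted p = 2.15e-08, or adjusted p = 0.552 with an estimated correlation), with 0 of 30 called also adjusted over the list alone.

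**Figure D4:**
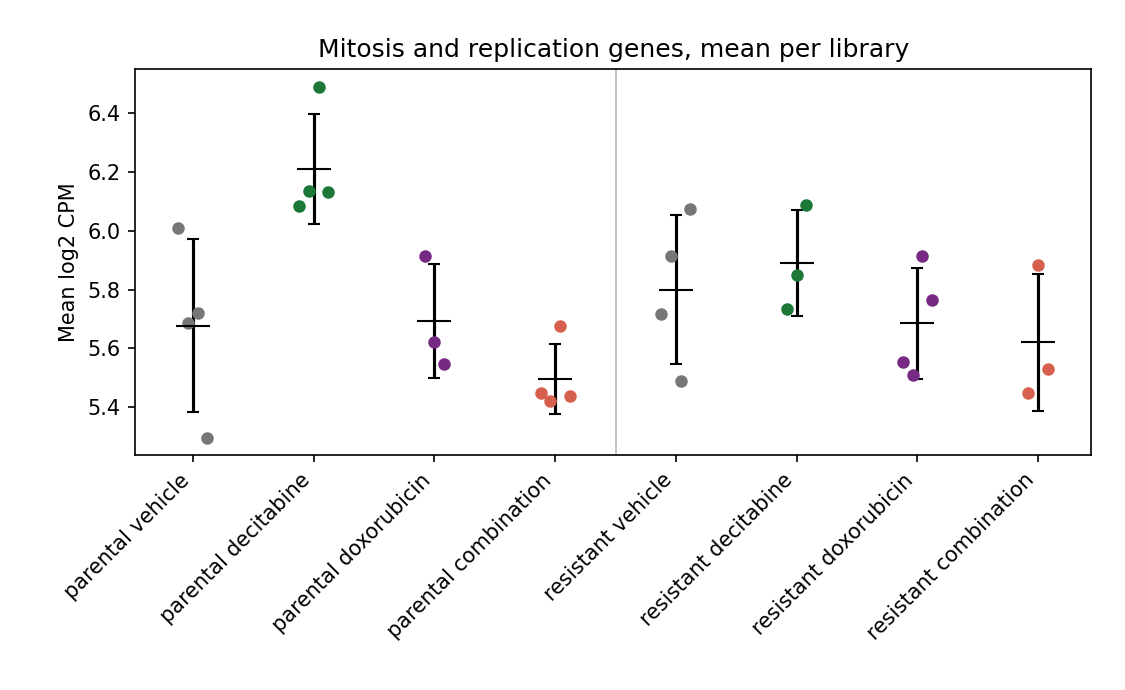
Mean log2 CPM of the mitosis and replication genes in each library (points), by group, with group means and SD. The parental decitabine libraries lie between 6.08 and 6.49, above the parental combination libraries between 5.42 and 5.68. The parental vehicle libraries lie between 5.30 and 6.01.

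The response to decitabine differed between the lines for 16 genes, 14 of them higher in the resistant line relative to the parental line. That direction was not kept without a filter (388 higher and 613 lower), and the numbers were nearly even by DESeq2 (150 and 141) and without parental vehicle 1 (154 and 145) or resistant decitabine 3 (74 and 62). FCGRT (ENSG00000104870, chromosome 19, 49506816 to 49526333), the neonatal Fc receptor, fell by 1.06 in parental and rose by 1.57 in resistant tumours, a difference of 2.63 (SE 0.35, adjusted p = 0.000333). FHL1, a LIM domain protein, had log2 values of -0.22 and 1.77, a difference of 2.00 (SE 0.37), and ITGBL1, with 1 count in resistant vehicle tumours, a fitted difference of 5.60 (SE 0.89). C16orf74 went the other way, at 0.82 and -1.05, a difference of -1.87 (SE 0.34). The count became 37 without parental decitabine 4, 299 without parental vehicle 1, 10 without parental vehicle 4, 42, 7 and 136 without resistant decitabine 1, 2 and 3, 44 without resistant vehicle 3, and 7 without the 2 libraries that stood apart. FCGRT, FHL1 and ITGBL1 stayed called in each fit, and 4 other genes named by the rule lost their call without at least 1 library, 3 of them without resistant decitabine 2. The response to doxorubicin differed for 0 genes in the edgeR test, with 1078 at an unadjusted p under 0.05, 32 by DESeq2 and 10 by voom, and 1 gene was called without parental doxorubicin 2, parental vehicle 2 or resistant doxorubicin 1. The response to the combination differed for 3 genes, NUP93, a nuclear pore protein, at -0.79 (SE 0.14), MMP16 at 1.66 (SE 0.31) and ITGBL1, named after its values were seen because it fell outside the rule, at 5.06. NUP93 and MMP16 lost their call in 7 and 9 of 15 fits with 1 library left out (adjusted p up to 0.139 and 0.172). With DESeq2's size factors the count was 5, of which 80% were higher, against 66.7%, and without a filter 339 were higher and 770 lower. The count of 3 became 0 without parental combination 1 or 2, parental vehicle 3 or resistant vehicle 1, 2 or 4, 27 without parental combination 3, 14 without parental vehicle 1, 6 and 273 (114 higher and 159 lower) without resistant combination 1 and 3, 5 without resistant vehicle 3, and 2 without parental combination 4, parental vehicle 4 or resistant combination 2.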

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

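The tests of small nuclear RNA and leukocyte-type genes, and the test of library measures as covariates for the mitosis genes, were chosen only after the result was seen.

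Parental combination tumours had 37 of 60 mitosis and replication genes called lower than parental decitabine tumours, with a median log2 of -0.70. A single library was argued against as the whole source, since 14 genes were called without parental decitabine 3 and 22 without parental combination 2, the 2 fewest over the 8 libraries left out in turn. Depth or RNA quality was argued against too: the difference in mean log2 CPM was -0.715 (95% interval -1.03 to -0.402) and -0.675 (-0.989 to -0.361) with the mitochondrial share as a covariate, the smallest of 4 measures. A covariate from the first component of the residuals, which gave 50 genes, was void because it is independent of the groups by construction. An effect of adding doxorubicin may therefore be a candidate explanation, and the mice, which the labels do not give, stay open.

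Small nuclear RNA genes were lower with decitabine, with medians of -0.86 in parental tumours (28 of 30 below 0) and -0.46 in resistant tumours (22 of 30), and since such RNA lacks a poly(A) tail, carry-over that differs between libraries could give the pattern. The median of small nucleolar RNAs minus that of small nuclear RNAs was 0.433 in parental (95% interval -0.15 to 0.814) and 0.483 in resistant tumours (-0.00841 to 1.42), and the mean correlation of residuals between these classes and replication histones was 0.448. Intervals of medians are over genes, not libraries, and cannot test carry-over. Replication histones, whose transcripts mostly lack the tail too, had medians of 0.159 (0.0839 to 0.597) in parental and 0.357 (-0.777 to 0.586) in resistant tumours. Less the change of the replication genes, they exceeded small nuclear RNAs by 0.665 (0.227 to 1.15) in parental tumours. That interval included 0 for the 9 histone genes not known to give transcripts with a tail as well (0.595, -0.419 to 0.948), while by summed CPM the excess in parental tumours was 0.826 (0.264 to 1.39) for all histones and 0.751 (0.103 to 1.4) for those 9, and that of small nucleolar RNAs 0.749 (0.209 to 1.29) in parental and 0.723 (0.14 to 1.31) in resistant tumours, sums in which 1 gene held 74.6% (all histones), 64.8% (nucleolar) and 58.8% (nuclear) of the counts. Carry-over and a response to decitabine therefore cannot be told apart from these counts. With doxorubicin the medians were -0.49 and -0.29.

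The summed CPM of 4 leukocyte-type genes (CD93, FCER1G, LAPTM5 and INPP5D), most of it LAPTM5, was higher in resistant decitabine than in resistant vehicle tumours by 0.97 on the log2 scale (0.55 to 1.37 over pairs of libraries). Other myeloid markers differed by 0.168 (-0.215 to 0.556), which is too wide to argue against reads from mouse leukocytes. TYROBP, abundant in myeloid cells, had 2 counts, C1QA 1 and ITGAM 2 in resistant decitabine tumours. That every library with decitabine lay above every library without it in 6 of 8 pairs of groups says nothing for a response of the tumour cells, since the 4 genes were chosen because they were higher with decitabine, and both explanations stay open.

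For other splits of the same libraries, chance could be excluded for these counts, each reached by 1 of 35 splits: 2718 between the lines (highest other split 255), 225 and 450 with decitabine in parental and resistant tumours (172 and 41), 139 and 152 with the combination (0 and 62), 41 and 89 for the combination against doxorubicin (1 and 13), and 895 for the combination against decitabine in parental tumours (1). The share was not under 0.05 for doxorubicin in parental tumours, where 2 of 35 splits gave at least 31 genes and the highest other gave 52. Nor was it in resistant tumours (0 genes, 35 of 35, highest other 1). The combination against decitabine in resistant tumours had 10 splits, too few for a share under 0.05. The real split gave 0 genes and the highest other 221, for a reason not tested. For the difference between the lines' responses to decitabine, 3 of 100 splits reached the 16 genes, a share under 0.05. The highest other split gave 377 genes, so chance was not excluded. For the combination, 3 of 100 reached the 3 genes (highest other 6), which does not exclude chance either. For doxorubicin, 100 of 100 splits reached 0 genes, with 2 in the highest other.

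In 31 of 327 groups of 4 libraries, 1 library lay apart from the others by more than Dixon's 95% critical ratio, where chance gives about 1 in 20 groups of continuous values. In 8 of the 31 the other 3 libraries had no count of the gene, which fixes the ratio, and the other 23 came from 319 groups; many genes had few counts, so these numbers were not compared with chance. For library measures these were the mitochondrially encoded share of parental decitabine 1 (4.04%) and the share of the 10 most counted genes in resistant vehicle 1 (10.2%). High in parental vehicle 1 were LCP1 (5.33 CPM), SSX1 (6.96), CSTA (0.232) and IL24 (0.696), and CLDN4 was low (30.8). Parental vehicle 2 was low in MIR100HG (94.5 CPM). Parental vehicle 3 was high in SMOC1 (0.514 CPM) and KCNU1 (0.257) and low in SOD2 (11.3). Parental vehicle 4 was high in PTPRN2 (0.228 CPM), GABRE (10.0), ABCC3 (11.6), ALDH1A3 (5.48) and FOS (56.8), and low in AMOT (9.58). ABCC3 was high in parental decitabine 2 (3.84 CPM), and CDK1 (209 CPM), ESCO2 (18.3) and NUP93 (183) in parental decitabine 3. High in resistant vehicle libraries were ID4 (0.253 CPM), IFI44 (11.9) and MMP1 (11.1) in 2, ABCB9 (56.5), OAS2 (36.4) and PECAM1 (7.24) in 3, and AMOT (0.226), ITGBL1 (0.226) and INPP5D (0.452) in 4. DKK1 was low in resistant doxorubicin 2 (112 CPM).

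The lines' responses to decitabine, as resistant minus parental log2 values in the edgeR interaction test, differed for FCGRT (2.63), ITGBL1 (5.60), FILIP1 (4.59), C16orf74 (-1.87), FHL1 (2.00), NUP93 (-0.73) and ZNF512B (1.89). FILIP1 did not pass without parental vehicle 4 (adjusted p = 0.0962), C16orf74 (0.0562) and NUP93 (0.0815) without resistant decitabine 2. ZNF512B did not pass without parental decitabine 1 (0.0754) or 2 (0.0792), parental vehicle 2 (0.0557) or 3 (0.0582), resistant decitabine 1 (0.0521) or 2 (0.0815), or resistant vehicle 1 (0.0599), 2 (0.0816) or 3 (0.0504). For the combination the differences were NUP93 (-0.79), ITGBL1 (5.06) and MMP16 (1.66). NUP93 did not pass without parental combination 1 (0.0826) or 2 (0.0565), parental vehicle 3 (0.096), resistant combination 2 (0.139), or resistant vehicle 1 (0.0542), 2 (0.116) or 4 (0.0702). MMP16 did not pass without parental combination 1 (0.0885) or 2 (0.102), parental vehicle 2 (0.0539), 3 (0.0989) or 4 (0.07), resistant combination 2 (0.172), or resistant vehicle 1 (0.0954), 2 (0.116) or 4 (0.0859).

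Of the gene lists, the responses to decitabine differed for interferon-stimulated (median 0.53), mitosis (-0.40), ribosomal protein (-0.33), oxidative phosphorylation (-0.42), repair (-0.24) and replication genes (-0.25), with 0 of these lists passing with an estimated correlation. Repair did not pass without parental vehicle 4 (adjusted p = 0.0908) or resistant decitabine 1 (0.0936), and replication without parental decitabine 3 (0.105), parental vehicle 4 (0.177), resistant decitabine 1 (0.26) or resistant vehicle 4 (0.0811). The responses to doxorubicin differed for interferon-stimulated (0.73), hypoxia (-0.36), ribosomal protein (-0.22), oxidative phosphorylation (-0.21), replication (-0.17), mesenchymal (-0.40) and ABCB1-neighbouring genes (0.0839), with 0 passing with an estimated correlation. Oxidative phosphorylation did not pass without parental vehicle 3 (0.0846), resistant doxorubicin 3 (0.0922) or resistant vehicle 4 (0.0677). Replication did not pass without parental doxorubicin 1 (0.374), parental vehicle 4 (0.418), resistant doxorubicin 1 or 2 (0.137 each), or resistant vehicle 2 (0.0818) or 4 (0.29). Mesenchymal genes did not pass without parental doxorubicin 3 (0.373), parental vehicle 3 (0.0591), resistant doxorubicin 1 (0.0752), 3 (0.0508) or 4 (0.103), or resistant vehicle 2 (0.0818) or 3 (0.115), and the neighbours of ABCB1 without parental doxorubicin 2 (0.063), parental vehicle 1 (0.0628), resistant doxorubicin 2 (0.0531) or 3 (0.112), or resistant vehicle 3 (0.0585). The responses to the combination differed for hypoxia (-0.61), ribosomal protein (-0.40), oxidative phosphorylation (-0.32), ABCB1-neighbouring (0.22) and interferon-stimulated genes (0.35), with 0 passing with an estimated correlation. Interferon-stimulated genes did not pass without parental combination 2 (0.0587), parental vehicle 2 (0.116) or 4 (0.18), resistant combination 1 (0.372) or 3 (0.125), or resistant vehicle 2 (0.305). The neighbours of ABCB1 did not pass without parental combination 3 (0.0773) or 4 (0.0867), parental vehicle 1 (0.134) or 2 (0.0687), resistant combination 2 (0.273) or 3 (0.072), or resistant vehicle 3 (0.0882).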

How the results depend on the processing

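Only the alternative without the 2 libraries that stood apart was chosen after the data were seen. Counts are in the order decitabine, doxorubicin and combination against vehicle, combination against doxorubicin and against decitabine, and the lines' differences in response, and values within 1.5 times are left out. The 2718 genes between the lines stayed within 1.5 times under each alternative (2043 to 3155) and library left out (2037 to 2542). Without a filter the counts were 942 (parental) and 1089 (resistant) for decitabine, 192 and 74 for doxorubicin, 884 and 783 for the combination, 305 and 543 against doxorubicin, 48 against decitabine in resistant tumours, and 1001, 108 and 1109 for the differences. The laxer CPM filter gave 1 for the combination difference. Voom with sample weights gave 1113 and 732 for decitabine, 1 for doxorubicin in resistant tumours, 324 for the combination and 94 and 1865 against the single drugs in parental tumours, and 77, 10 and 0 for the differences. DESeq2 gave 489 for decitabine and 155 for doxorubicin in parental tumours, 321 and 235 for the combination, 80 against doxorubicin in parental tumours, and 291, 32 and 214 for the differences. With the groups of the comparison alone, a fit with fewer libraries, the counts were 2 and 104, 0 and 4, 64 and 66, 49 for the combination against doxorubicin in resistant tumours, and 1 and 0 for the decitabine and combination differences. DESeq2's size factors gave 5 genes for the combination difference, and upper quartile scaling 32 and 1 for the decitabine and doxorubicin differences. Without the 2 libraries the counts were 96 and 162, 3, 85 and 363, 65 and 193, and 7 for the decitabine difference. The cause of these shifts was not tested. With 1 library left out, the ranges were 6 to 608 and 146 to 728 for decitabine, 1 to 124 and 0 to 0 for doxorubicin, 53 to 154 and 49 to 156 for the combination, 7 to 34 and 52 to 74 against doxorubicin, 210 to 1151 and 0 to 0 against decitabine, and 7 to 299, 0 to 1 and 0 to 273 for the differences. Replicate numbers did not pair the libraries: over 94 pairs with the same number the mean correlation of deviations was 0.0057 (-0.461 to 0.427), 27 pairs exceeded 0.1, and 8 of 29 libraries correlated best with one of their own number. A replicate block gave 147 genes for decitabine and 3 for doxorubicin in parental tumours, 1 each for the doxorubicin and combination differences, and 18 shared decitabine genes. Shared decitabine genes (28) numbered 138 without a filter, 15 without the 2 libraries, and 4 to 32 with 1 library left out. The 57 list calls in the comparisons with vehicle and between the lines became 0 with an estimated correlation, and 51 to 64 with 1 library left out. Fry called 33 lists there, 10 against 3 between the lines and 0 against 8 and 10 with doxorubicin, and of the 113 list calls in all comparisons 39 held with fry. The median decitabine log2 of genes lower in the resistant line (0.067) was 0.096 without a filter, 0.13 with shared controls, 0.161 for genes with an absolute log2 of at least 1, and 0.034 to 0.092 with 1 library left out. Genes higher in the resistant line turned from below to above 0, at 0.001 with the replicate block and without resistant decitabine 2, 0.055 without parental vehicle 3 (lowest with 1 library left out -0.052, without parental vehicle 2) and 0.084 for an absolute log2 of at least 1, and stayed below 0 without a filter (-0.101) and with shared controls (-0.108). Other values that turned were not called: DNMT3A with decitabine in parental tumours (-0.01 without parental decitabine 3, up to 0.21 without parental vehicle 3), TOP2A with doxorubicin in parental (-0.04 without parental doxorubicin 1, -0.03 without parental vehicle 4, up to 0.16) and resistant tumours (0.03 without resistant doxorubicin 2, down to -0.17), and CDKN1A with doxorubicin in resistant tumours (0.01 with upper quartile scaling, the block, voom or without resistant vehicle 1, 0.09 without resistant doxorubicin 3, 0.06 without resistant vehicle 3, down to -0.09). The hypoxia list with doxorubicin in resistant tumours turned without resistant doxorubicin 3 (adjusted p = 0.831, against 0.0018 without resistant doxorubicin 2), and the lymphoid list for the combination against doxorubicin in parental tumours without a filter (adjusted p = 0.531). Over 1655 fits of the called genes among those checked with 1 library left out, the call held in 1278. It held in 123 of 198 with the groups of the comparison alone, in 165 of 211 without the 2 libraries, in 192 of 211 with the replicate block and in 197 of 211 with voom, and in at least 204 with each other scaling, filter or tool. At about 4600007 counts per library, genes with few counts, such as ABCB1, could not be compared, and no scaling moved the median of all genes by more than 0.0497.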

Other observations

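CD93 had 0 counts in each of the 4 groups without decitabine and 40, 44, 60 and 77 counts in the parental decitabine, parental combination, resistant decitabine and resistant combination groups. INPP5D had 7, 6, 5 and 3 counts in the parental vehicle, parental doxorubicin, resistant vehicle and resistant doxorubicin groups, and 81, 115, 70 and 49 in those 4 groups with decitabine. These counts were looked up after the differences were seen.

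Hypoxia and glycolysis genes, which had a median log2 of -0.91 with decitabine in resistant tumours, had a median of 0.35 for the combination against decitabine in that line (adjusted p = 4.01e-11, or adjusted p = 0.552 with an estimated correlation), with 0 of 29 called and 1 higher adjusted over the list alone. Both comparisons use the same decitabine libraries, so their opposite signs are not independent. Cholesterol synthesis genes had a median of -0.40 for the combination against doxorubicin in parental tumours (adjusted p = 6.7e-07, or adjusted p = 0.162 with an estimated correlation), with 0 of 24 called and 1 lower adjusted over the list alone.

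Other lists passed with the preset correlation where the combination was compared with 1 drug, and 0 of them with an estimated correlation (adjusted p = 0.129 to 0.92). Against doxorubicin in parental tumours, antigen presentation (median log2 0.477, 1 of 19 genes called higher), NF-kB (0.534), cancer-testis, luminal or basal (0.225, 1 of 10 called higher), apoptosis (0.142) and lymphoid genes (1.06) were higher, and mitosis (-0.178) and replication genes (-0.255) lower. Apoptosis did not pass without parental combination 1 (adjusted p = 0.0512) or 3 (0.0651) or parental doxorubicin 2 (0.154), lymphoid genes without parental combination 3 (0.0916) or parental doxorubicin 2 (0.156), and mitosis without parental doxorubicin 1 (0.694). Against doxorubicin in resistant tumours, interferon-stimulated (0.361) and muscle genes (1.38) were higher, and hypoxia (-0.244) and ribosomal protein genes (-0.24) lower. Muscle genes did not pass without resistant combination 2 (0.159) or 3 (0.0768) or resistant doxorubicin 1 (0.0821) or 4 (0.11), or with DESeq2's size factors (0.0564), and hypoxia without resistant combination 1 (0.0549) or 2 (0.276) or resistant doxorubicin 1 (0.0721), 2 (0.187) or 4 (0.133). Against decitabine in parental tumours, repair (-0.395, 12 of 29 called lower), ABCB1-neighbouring (-0.272, 5 of 24), methylation (-0.134, 3 of 19), nucleoside (-0.238, 3 of 17) and cholesterol genes (-0.285, 1 of 24) were lower, and antigen presentation (0.456, 5 of 19 called higher), NF-kB (0.619, 4 of 22), ribosomal protein (0.299, 4 of 30) and mesenchymal genes (0.138, 1 of 23) higher. Mesenchymal, methylation and nucleoside genes did not pass without 5, 4 and 3 of the 8 libraries (adjusted p up to 0.149, 0.101 and 0.107). Against decitabine in resistant tumours, where edgeR called 0 genes, replication (-0.268), repair (-0.17), methylation (-0.155) and germline genes were lower, and antigen presentation (0.237), unfolded protein response (0.153), ribosomal protein (0.167) and mesenchymal genes (0.138) higher. Of these, replication passed whichever library was left out, and the others did not pass without 1 to 5 of the 6 libraries (adjusted p up to 0.861).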
